A study of Mus musculus with 8 samples.

How the data were processed

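Total RNA of whole retina from 4 heterozygous and 4 homozygous mice was labelled with a 3′ in vitro transcription kit and hybridised to 1-colour oligonucleotide arrays, 1 array per mouse, per the labels' protocols. The values analysed are the log2 expression values the authors deposited, a single table of 22690 probe sets by 8 samples. The authors made them with RMA, per the submitters' processing notes. The software and version that ran RMA, its background step and the probe definitions are not given in the sources used here. The values ran from 0.54 to 13.1 with array medians from 3.57 to 3.66. That range lies below the 16 that log2 of a 16-bit scan allows and above the 11.1 that a natural logarithm would allow. The table held no detection calls, so the signal of genes that an animal should lack served as a guide. The Y-linked genes Eif2s3y and Kdm5d measured 0.68 to 0.99 in females, and Xist measured 2.49 to 3.14 in males, so values below about 3 were read as within the range of background. Because array values are compressed at low signal, differences of genes in that range are likely understated.

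Of the probe sets, 64 were array controls and were left out of all tests. Gene names came from the annotation of the platform. In it 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none, and no gene was named from a probe set with several. Symbols were updated through the Entrez identifier to the gene table of assembly GRCm38.p6, which held 12369 of the 12393 genes. No coordinates are given, since the table of values names no genome build. For a gene with several probe sets the one with the highest mean over all 8 arrays was used. Probe sets that disagreed in sign are named where the gene is.

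Groups and sexes were taken from the genotype and sex labels, and replicate numbers from the titles. The labels state biological replicates. Nothing in the sources used here gives litters, dissection or scan days, so these could not be tested as batches. The main model was limma's lmFit and eBayes with an intensity trend (limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8), with genotype as its term for the genotype comparison, genotype and sex for the sex comparison, and their interaction for the test of a genotype difference that depends on sex. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The 32 gene lists held 565 entries, 477 of them measured, and were tested with limma's camera at the preset correlation of 0.01, adjusted over the 32 lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of each animal's list median. Each list was also tested by adjusting its members' limma p-values over the list alone. Quality measures were compared with exact two-sided permutation tests over all assignments of 4 and 4 arrays.

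The models, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The alternatives that leave out the male or the female homozygotes, the permutation of list medians and the list test of the interaction were added afterwards. The rule named Pex1; the genes past the genotype threshold, filled up to 20 in order of p; in each list up to 4 members past the threshold or else the 2 with the smallest p; Gfap, Rho, Opn1sw and Opn1mw; Xist, Ddx3y, Eif2s3y, Kdm5d, Uty and the 5 others with the smallest p for sex; and up to 6 genes past the threshold for the interaction. Other genes the text names were singled out after their values were seen. Pex1, Rho and Ddx3y had no probe set with 1 gene symbol in the annotation used, so the level of the targeted gene was not analysed here, nor were those of Rho and Ddx3y. The allele is a missense change, so its RNA level would not have checked the labels.

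The fits were tested on simulated data before they were applied. Known differences of 3 sizes were added to 67, 67 and 66 of the 12393 genes with the spread that the real arrays show within genotype and sex. For the genotype comparison 41.8% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 98.5% of those changed by 2 were recovered. For the sex comparison the shares were 38.8%, 97.0% and 100%, and for the interaction 1.49%, 22.4% and 97.0%. In the list test 2 of 2 lists shifted by 0.5 were recovered, with 1 false list of 32. The genes were simulated as independent of each other, so this does not give the rate of false lists where the genes of a list move together. The simulated spread leaves out differences between animals of 1 genotype that follow sex or dissection, so the shares are upper limits for the real genotype comparison.

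Alternatives changed the covariates, the probe set rule, the filter on dim genes, the normalization between arrays, the variance model, array weights, the test, the threshold and the set of arrays, including each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.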

Results

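Gene expression was measured in whole retinas of 8 mice that carried a hypomorphic allele of Pex1 (G844D). Pex1 encodes an ATPase needed for the import of proteins into peroxisomes. Of the mice, 4 were homozygous for the allele (2 males and 2 females) and 4 were heterozygous and served as controls (3 males and 1 female). All were 124 days old, and the labels give each retina sample as a separate biological replicate. The titles of the homozygous samples also carry the word control, while their genotype, source and description fields all state homozygote, and the genotype field was followed here. The comparison asks which transcripts differ between the genotypes in a model of peroxisome biogenesis disorder with retinal degeneration.

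The values are RMA expression values on the log2 scale, and 12393 genes were tested. The median value per array lay between 3.57 and 3.66, and the correlation between any pair of arrays, taken over the 12393 genes, lay between 0.978 and 0.996. The closest pair was homozygote replicates 3 and 4, both female. The 3′ minus 5′ difference of the beta-actin control probe sets, which grows as RNA degrades, was 2.79 ± 0.19 in heterozygotes and 2.41 ± 0.21 in homozygotes (SD, n = 4 each). That difference of -0.38 gave p = 0.0286 in an exact two-sided permutation test, the smallest p that 4 against 4 arrays allow. The same measure for Gapdh was 0.93 ± 0.35 and 0.67 ± 0.14 (exact p = 0.286). The number of arrays limits the precision of every value below.

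Transcripts of cone photoreceptors were lower in homozygotes. Arr3, the cone arrestin, fell by 1.45 on the log2 scale (SE 0.16), to 0.367 of the heterozygote level. Pde6h, the inhibitory subunit of the cone phosphodiesterase, fell by 1.16 (SE 0.14), and Opn1mw, the middle-wavelength cone opsin, fell by 0.90 (SE 0.10), with n = 4 per genotype. For these 3 genes each of the 4 homozygotes lay below each of the 4 heterozygotes. Arr3 measured 6.96 ± 0.17 in heterozygotes and 5.51 ± 0.33 in homozygotes, Pde6h 9.86 ± 0.22 and 8.70 ± 0.24, and Opn1mw 6.54 ± 0.03 and 5.65 ± 0.16 (SD). They were the only genes of 12393 past the threshold in limma, at adjusted p = 0.0158 for Arr3 and Opn1mw and 0.0225 for Pde6h. Of the 12 measured members of the cone list, 3 fell, none rose and 9 did not pass over all genes tested. Adjusted over the list alone, 6 members fell. The other 3 were Gnat2, the cone transducin alpha subunit (-0.98, SE 0.14, adjusted p = 0.0703 over all genes), Opn1sw, the short-wavelength opsin (-1.14, SE 0.18, adjusted p = 0.135), and Cngb3, a cone channel subunit (-0.75, SE 0.15, adjusted p = 0.520). Gnb3, a G-protein beta subunit shared by cones and bipolar cells, had the opposite sign (0.65, SE 0.28, adjusted p = 0.851), and Pde6c, the catalytic cone phosphodiesterase subunit, measured -0.13 (SE 0.39).

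The list as a whole shifted down against the other genes, with a median of -0.51 (camera adjusted p = 3.06e-10, and adjusted p = 0.233 with an estimated correlation). Its rotation test, fry, which asks whether the members move one way on balance, gave adjusted p = 0.0331. The median of the list per animal was -0.62 and -0.76 in the 2 homozygous males, -0.42 and -0.40 in the 2 homozygous females, and between -0.15 and 0.16 in the heterozygotes. The cone list was the only one of 32 whose medians separated the genotypes (exact permutation p = 0.0286, the smallest possible, and adjusted p = 0.549 over the lists). Such separation arises by chance in 2.86% of cases, so 1 list of 32 is about what chance gives. The difference in the actin 3′ minus 5′ value also went along with the genotype groups. The differences moved little when 1 array was left out (-1.59 to -1.34 for Arr3, -1.26 to -1.05 for Pde6h and -0.94 to -0.82 for Opn1mw), but with fewer samples the calls were lost: without any 1 of heterozygote replicates 1, 2, 3 and 4 or homozygote replicate 4 no gene passed, and the lowest adjusted p was 0.0655, 0.1004, 0.0514, 0.0853 and 0.0531. Without homozygote replicate 1 only Opn1mw of the 3 passed (adjusted p = 0.0276, against 0.0964 for Arr3 and 0.150 for Pde6h), and without homozygote replicate 2 Pde6h did not (adjusted p = 0.0684). All 3 calls were lost with the replicate number as a block (adjusted p = 0.0707) and without moderation of the variances (0.4355 to 0.9143). Pde6h also lost its call without the intensity trend (adjusted p = 0.0652) and with the male homozygotes left out (0.112), and Opn1mw lost its call in males only (0.0541).

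**Figure D1:**
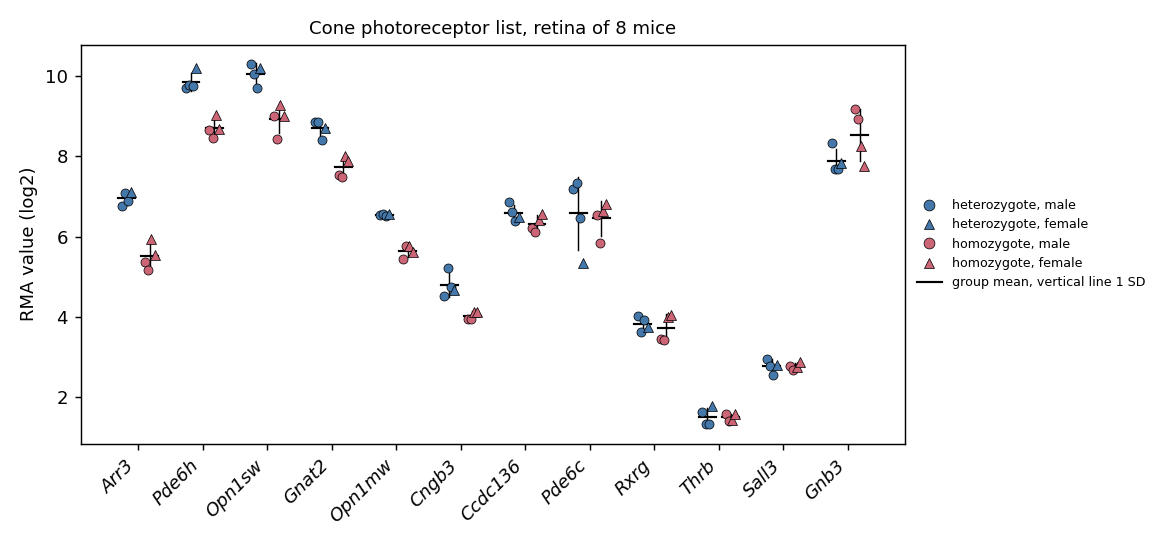
Expression of the 12 measured cone-list genes in each of the 8 retinas (vertical axis, RMA value on the log2 scale), with heterozygotes in blue, homozygotes in red, males as circles and females as triangles. Horizontal bars are group means and vertical lines 1 SD (n = 4 each). Arr3, Pde6h, Opn1sw, Gnat2, Opn1mw and Cngb3 show no overlap between genotypes, and Gnb3 has the opposite sign.

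Rod transcripts differed little. Of 14 measured members of the rod list, none passed the threshold over all genes and 0 adjusted over the list alone, although 13 of the 14 estimates lay below 0. Nrl, the transcription factor that sets rod fate, measured 11.39 ± 0.15 in heterozygotes and 11.18 ± 0.15 in homozygotes (difference -0.21, SE 0.10, n = 4 each). Pde6a, a rod phosphodiesterase subunit, differed by -0.19 (SE 0.13), or -0.10 without heterozygote replicate 2 and -0.12 without homozygote replicate 2, and Nrl by -0.14 without the latter. The list's median of -0.12 passed in camera (adjusted p = 0.0287, and 0.720 as the adjusted p with an estimated correlation). That call was lost without any 1 of heterozygote replicates 1, 2 and 4 or homozygote replicates 2 and 3 (adjusted p from 0.0788 to 0.346). It was also lost with array weights, in males only and with the homozygotes of either sex left out (adjusted p from 0.0648 to 0.109).

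The other lists of retinal neurons and the list of Muller glia did not pass in camera in the main model. Of 27 alternatives, the Muller list passed in 3 (lowest adjusted p = 0.00114), the bipolar list in 2 (0.04525) and the ganglion cell list in 1 (0.0320). The 20 genes shared by both photoreceptor types had a median of -0.06 (adjusted p = 0.248, and 0.00222 without heterozygote replicate 3), with Rdh12, a retinol dehydrogenase, at -0.24 (SE 0.09) and Rbp3, the interphotoreceptor retinoid-binding protein, at 0.27 (SE 0.11). The medians were -0.04 for the 9 genes of the photoreceptor ribbon synapse (adjusted p = 0.472), -0.06 for 12 bipolar genes (0.472), -0.01 for 14 amacrine and horizontal genes (0.970), -0.01 for 12 ganglion cell genes (0.434) and 0.11 for 14 Muller glia genes (0.171). At the synapse, Unc13b, a vesicle priming factor, measured -0.24 (SE 0.12) and Cplx3, a complexin, -0.14 (SE 0.09), which became -0.15 for Unc13b without heterozygote replicate 2 and -0.09 for Cplx3 without homozygote replicate 2. Among bipolar genes, Trpm1, the channel of ON bipolar cells, measured -1.31 (SE 0.61), and -0.57 without heterozygote replicate 3, in which it stood at 5.95 against 2.49 to 3.73 in the other heterozygotes. The same retina had the highest value of the melanin gene Dct (9.71). The transcription factor Vsx1 measured 0.32 (SE 0.14). The horizontal cell factors Lhx1 (-0.25, SE 0.18; -0.12 without heterozygote replicate 2) and Prox1 (0.11, SE 0.09, and 0.05 without homozygote replicate 3) and the ganglion cell genes Gap43 (0.30, SE 0.11) and Nefm (0.18, SE 0.14, and 0.10 without heterozygote replicate 1) did not pass, nor did Abca8a, a transporter of Muller cells (-0.40, SE 0.17). Crym, a thyroid hormone-binding crystallin placed in the Muller list, measured 6.55 ± 0.15 in heterozygotes and 7.91 ± 0.78 in homozygotes (1.36, SE 0.31, adjusted p = 0.639) and was the 1 Muller gene that passed when adjusted over the list alone. No gene of these lists passed over all genes tested, and 0 passed adjusted over the list alone in the other 5.

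Genes of gliosis and of microglia had higher values in homozygotes, by amounts that differed widely between the 4 animals. The gliosis list had a median difference of 1.43 over 19 genes, the microglia and macrophage list 0.87 over 20 and the interferon list 0.64 over 16. In the main model no single member passed over all genes tested. Under alternatives Edn2 passed in 3 of 25 (lowest adjusted p = 0.00384), Osmr in 3 of 24 (0.00718), Ctss in 2 of 25 (0.00117) and Gbp2 in 2 of 23 (0.00352). Adjusted over the list alone, 4 gliosis genes rose (Edn2, Osmr, Stat3 and Cebpd), 10 microglia genes rose and 0 interferon genes did. Edn2, an endothelin that stressed photoreceptors release, measured 3.40 ± 1.07 in heterozygotes and 7.02 ± 1.68 in homozygotes (3.62, SE 0.76, adjusted p = 0.520). Osmr, the oncostatin M receptor, differed by 1.77 (SE 0.42, adjusted p = 0.671). Ctss, a lysosomal protease of microglia, differed by 1.45 (SE 0.38) and P2ry12, a receptor of resting microglia, by 0.46 (SE 0.11), and each lay above all heterozygotes in all 4 homozygotes. P2ry12 stayed below 2.4 in every animal, within the range of background. Oasl2 differed by 1.17 (SE 0.34) and Gbp2 by 1.79 (SE 0.62), both interferon-induced genes. Gfap, the intermediate filament of reactive glia, measured 2.49 ± 0.21 and 2.43 ± 0.18, which is also within the range of background, and its second probe set had the opposite sign.

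In camera the microglia list passed at adjusted p = 4.94e-15, the gliosis list at 4.67e-13 and the interferon list at 2.53e-09, each with adjusted p = 0.5002 with an estimated correlation. Fry gave adjusted p = 0.644 for each. Exact permutation of the list medians gave, in the same order, p = 0.0571, 0.143 and 0.143 (adjusted p = 0.549, 0.571 and 0.571). The median of the gliosis list per animal was 2.33 and 2.66 in homozygote replicates 1 and 2, both male, against 0.33 and 0.06 in replicates 3 and 4, both female, while heterozygotes lay between -0.23 and 0.49. For microglia genes the same medians were 1.33, 2.10, 0.29 and 0.12, with heterozygotes from -0.16 to 0.25, and for interferon genes 0.57, 1.37, 0.26 and 0.07, with heterozygotes from -0.18 to 0.44. Without homozygote replicate 2 the mean difference of the microglia list was 0.59 instead of 0.92 and that of the interferon list 0.39 instead of 0.65, and both still passed (adjusted p = 1.36e-10 and 2.45e-06). With the male homozygotes left out, a comparison chosen after the data were seen, the gliosis list's mean difference was 0.33 (adjusted p = 0.0320), that of the microglia list 0.22 (adjusted p = 0.00998) and that of the interferon list 0.17 (adjusted p = 0.0632). These camera p-values used the preset correlation, and the medians of the 2 homozygous females overlapped those of the heterozygotes. They do not establish a rise in the females. The interferon call was also lost with genes below the median signal left out (adjusted p = 0.0753).

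**Figure D2:**
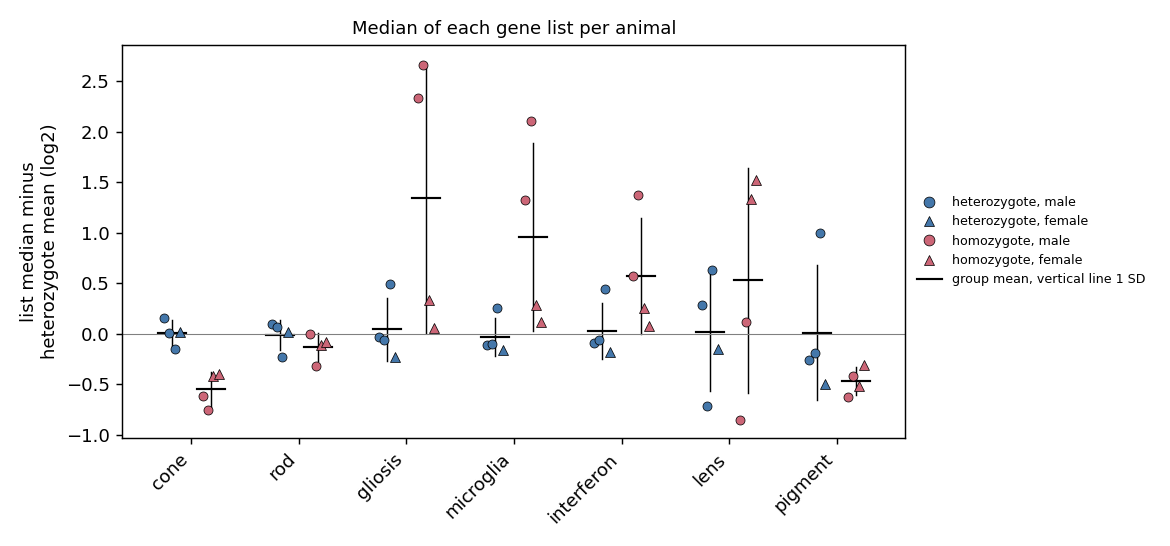
Median over the genes of 7 lists in each retina, after subtraction of each gene's heterozygote mean (vertical axis, log2), with the same colours and symbols for genotype and sex. Bars are group means and vertical lines 1 SD (n = 4 each). The cone medians of the homozygotes (-0.76 to -0.40) lie below all heterozygotes, the gliosis and microglia medians are highest in the 2 male homozygotes and the lens medians in the 2 female homozygotes.

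No gene of the peroxisomal lists passed over all genes tested. Ehhadh, the peroxisomal bifunctional enzyme of beta-oxidation, measured 2.72 ± 0.39 in heterozygotes and 3.92 ± 0.34 in homozygotes (1.203, SE 0.22, adjusted p = 0.351, n = 4 each), and all 4 homozygotes lay above all heterozygotes. It was the 1 of 21 measured genes of peroxisomal beta- and alpha-oxidation that rose when adjusted over the list alone. Acaa1b, a peroxisomal thiolase, differed by 1.34 (SE 0.47). Cyp4a14, a fatty acid hydroxylase induced through PPAR alpha, measured 1.97 ± 0.18 and 3.73 ± 0.56 (1.76, SE 0.24, adjusted p = 0.0703) and was the 1 of 19 genes of the PPAR alpha and mitochondrial fatty acid list to rise when adjusted over the list alone. Without homozygote replicate 1 it passed over all genes (adjusted p = 0.00131). The heterozygote values of Cyp4a14, and most of those of Ehhadh and Acaa1b, lie within the range of background, so the sizes of these differences are uncertain. Slc25a20, the carnitine carrier of mitochondria, differed by -0.47 (SE 0.14).

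The oxidation list passed in camera with a median of 0.04 and a mean of 0.17 (adjusted p = 0.0378, and adjusted p = 0.5002 with an estimated correlation), and the call was lost without any 1 of heterozygote replicates 1 and 2 or homozygote replicates 1, 2 and 3 (adjusted p from 0.0588 to 0.417). It was also lost under 10 other settings, among them both filters on dim genes, array weights and chromosome 5 left out (adjusted p from 0.0537 to 0.529). The PPAR alpha list did not pass (median 0.06, adjusted p = 0.109, and 0.0394 without heterozygote replicate 3), though fry found change in either direction (adjusted p = 0.0092). The 11 measured peroxins, the proteins that build peroxisomes, had a median of -0.01 (adjusted p = 0.956), with Pex6, the partner of Pex1, at -0.13 (SE 0.09, and -0.08 without homozygote replicate 1) and Pex3 at 0.12 (SE 0.12, and 0.03 without heterozygote replicate 1). The 4 measured genes of ether lipid synthesis had a median of 0.03 (adjusted p = 0.796), with Far1 at -0.05 (SE 0.15, with 2 of 5 probe sets of opposite sign) and Tmem189, the plasmalogen desaturase, at 0.08 (SE 0.14, with 1 of 3 opposite), and without 1 array they ranged from -0.17 to 0.06 for Far1 and from 0.01 to 0.16 for Tmem189. The 23 other peroxisomal genes had a median of -0.06 (adjusted p = 0.796), with Pmvk, an enzyme of the mevalonate pathway, at 0.74 (SE 0.22) and Agxt, a transaminase near background here, at -0.27 (SE 0.09). The 3 lists had 0 genes past the threshold over all genes and 0 adjusted over the list alone.

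Lipid synthesis and stress lists shifted by less than 0.2 in the median. Fdps, farnesyl diphosphate synthase, measured 5.88 ± 0.15 in heterozygotes and 6.31 ± 0.17 in homozygotes (0.43, SE 0.11, with a second, dim probe set of opposite sign). Hmgcs1, the synthase before HMG-CoA reductase, differed by 0.16 (SE 0.10; 0.10 without heterozygote replicate 4), and 13 of the 15 measured genes of cholesterol synthesis had estimates above 0. Fads2, the delta-6 desaturase of polyunsaturated fatty acids, differed by 0.64 (SE 0.15, adjusted p = 0.648) and was the 1 of 19 genes of fatty acid synthesis that rose when adjusted over the list alone, while Elovl2, which elongates such fatty acids, differed by -0.24 (SE 0.08). Atf3, a stress-induced transcription factor, differed by 0.96 (SE 0.33), with 1.65 in males and 0.20 in females. Sdf2l1, a chaperone cofactor, differed by 0.40 (SE 0.20), Fas, a death receptor, by 0.88 (SE 0.27) and Casp8, its caspase, by 0.33 (SE 0.15). Without homozygote replicate 2, Atf3 measured 0.63, Sdf2l1 0.25 and Casp8 0.17, and the mean of the cell death list 0.12 instead of 0.19. The lists of cholesterol synthesis (median 0.07, adjusted p = 0.0244), the unfolded protein and integrated stress response (0.08 over 21 genes, adjusted p = 0.00893) and cell death (0.11 over 13 genes, adjusted p = 0.00525) passed in camera. Their adjusted p with an estimated correlation was 0.535, 0.5002 and 0.233. No member of the 3 lists passed over all genes and 0 passed adjusted over the list alone. The cholesterol call was lost without any 1 of heterozygote replicates 1 and 4 or homozygote replicates 2, 3 and 4 (adjusted p from 0.0667 to 0.187, with a mean of 0.06 instead of 0.09 without the first), and the stress call without heterozygote replicate 1 or homozygote replicate 2 (adjusted p = 0.181 and 0.0679). With genes of mean under 5 left out none of the 3 passed (adjusted p = 0.0875, 0.308 and 0.426), nor with genes below the median signal left out (0.0753, 0.0753 and 0.290), and other settings also ended the calls, at up to 0.347 for cholesterol, 0.279 for stress and 0.233 for cell death, the last 2 with the male homozygotes left out.

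Lists that did not pass included fatty acid synthesis, elongation and desaturation (median -0.03 over 19 genes, adjusted p = 0.796) and oxidative stress with NRF2 targets (0.06 over 18, adjusted p = 0.186), in which Hmox1, heme oxygenase 1, differed by 0.85 (SE 0.33; 0.09 in males and 1.78 in females, and 0.54 without homozygote replicate 3) and Txnip, which binds thioredoxin, by 0.42 (SE 0.20, with 1 of 2 probe sets opposite). Oxidative phosphorylation had a median of 0.00 over 20 genes (adjusted p = 0.796), with Cox6a1 at -0.16 (SE 0.07) and Cyc1 at -0.19 (SE 0.08). Immediate early genes had a median of -0.05 over 15 (adjusted p = 0.956), and adjusted over the list alone Jun rose (0.62, SE 0.15) and Dusp1, a phosphatase of MAP kinases, fell by 0.39 (SE 0.10). The 15 clock genes had a median of -0.02 (adjusted p = 0.956), with Bhlhe40 at 0.21 (SE 0.13, and 0.14 without heterozygote replicate 4) and Npas2 at -0.15 (SE 0.10, with 1 of 2 probe sets opposite, and -0.24 without homozygote replicate 1). The 28 measured genes near Pex1 on chromosome 5 had a median of -0.03 (adjusted p = 0.970), with a mean of 0.09. Steap4, which is 1 of them, measured 2.91 (SE 1.28), with 5.80 in males and 0.07 in females, and Tmem243 measured 0.23 (SE 0.13). Without homozygote replicate 1 the value of Steap4 was 1.91, and without homozygote replicate 2 that of Tmem243 was 0.10. These lists had 0 members past the threshold over all genes, and of them fatty acid synthesis (1) and immediate early genes (2) had members past it adjusted over the list alone.

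Markers of tissues that surround the retina differed between animals of both genotypes. Dct, an enzyme of melanin synthesis, measured 7.56 ± 1.64 in heterozygotes and 4.29 ± 0.74 in homozygotes (-3.28, SE 0.68, adjusted p = 0.520, n = 4 each), while Rgr, a pigment epithelium opsin, measured 4.90 ± 0.38 and 5.90 ± 0.64 (1.00, SE 0.29). Adjusted over the list alone, Dct fell and Rgr rose, and 0 of the 11 measured genes of pigment epithelium and melanocytes passed over all genes. The list passed in camera with a median of -0.47 (adjusted p = 0.0378, and adjusted p = 0.720 with an estimated correlation). Without heterozygote replicate 3 its mean was -0.31 instead of -0.75. The call was lost without any 1 of heterozygote replicate 3 and homozygote replicates 1, 3 and 4 (adjusted p from 0.0708 to 0.314), and under 11 other settings, among them sex in the model and both filters on dim genes (0.0541 to 0.520). The 13 lens genes had a median of 0.36 and a mean of 0.90 (adjusted p = 0.00525, and adjusted p = 0.720 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone. That call was lost without any 1 of heterozygote replicate 2 and homozygote replicates 3 and 4 (adjusted p from 0.135 to 0.486), where the mean was 0.51 and 0.52 without homozygote replicates 3 and 4 (and 1.47 without homozygote replicate 1), and in males only or with the female homozygotes left out (0.306 and 0.445).

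Other cell types gave no list past the threshold. Blood genes had a median of 0.02 over 7 (adjusted p = 0.955). Alas2, the heme synthesis enzyme of red cells, was the 1 that fell adjusted over the list alone, from 3.02 ± 0.47 to 1.80 ± 0.20 (-1.22, SE 0.21, adjusted p = 0.257 over all genes), near background in both genotypes. Of the 7 blood genes, 6 averaged below 3, near background. Hbb-b1, Hbb-bs, Hbb-bt and Gypa had no probe set with 1 gene symbol. The list therefore does not settle whether red-cell transcripts differed between the genotypes. The 14 endothelial and pericyte genes had a median of 0.07 (adjusted p = 0.0780, and 0.00644, 0.0288 and 0.0250 without heterozygote replicates 2 and 3 and homozygote replicate 4 in turn), with Vwf at 0.78 (SE 0.21) and Kdr at 0.29 (SE 0.13), or 0.18 without homozygote replicate 1, in which it stood at 7.29 against 6.81 to 6.89. The medians were -0.04 for 9 oligodendrocyte genes (adjusted p = 0.3996, with the myelin genes Mobp at -0.20, or -0.13 without heterozygote replicate 1, and Mag at -0.20), -0.01 for 15 genes of eye muscle, sclera and choroid (0.773, with Ckm at -0.25 and Lum at -0.58, or -0.20 without heterozygote replicate 3) and -0.70 for the 4 sex-linked controls (0.796), a list that follows the unequal sexes of the groups. The median, the mean and the test differed in sign for amacrine and horizontal cells, ganglion cells, blood, fatty acid synthesis, immediate early genes, the clock and the genes near Pex1. Altogether 11 of 32 lists passed with the preset correlation and 0 with an estimated one.

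The genes that came next in order of p did not pass. Fabp7, a fatty acid-binding protein of glia, measured 3.93 ± 0.57 in heterozygotes and 2.48 ± 0.34 in homozygotes (-1.45, SE 0.27, adjusted p = 0.351). Mest, an imprinted gene of the hydrolase family, differed by 0.89 (SE 0.19), Igfbp1, an insulin-like growth factor-binding protein, by 1.05 (SE 0.23) and Aldh1l1, a folate enzyme of glia, by 0.55 (SE 0.12), each at adjusted p = 0.520. Clasp2 (0.59, SE 0.13), Dusp8 (0.51, SE 0.11), Ly75 (0.57, SE 0.11), Pcdhb19 (0.47, SE 0.09) and Ect2 (-0.93, SE 0.19) had adjusted p between 0.485 and 0.540. Ly75, Pcdhb19 and Ect2 stayed below 3 in every animal, within the range of background. Of further probe sets, 1 of Aldh1l1 and 2 of Clasp2 had the opposite sign. Over all 12393 genes, 5 passed at an adjusted threshold of 0.10 and 716 at an unadjusted p under 0.05 (364 higher and 352 lower, with 620 expected by chance). The 4 homozygotes lay all above or all below the heterozygotes for 395 genes (3.19%, against 2.86% by chance).

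Sex differences, tested to check the labels, were led by genes of the sex chromosomes. Xist, the RNA that silences an X chromosome, measured 9.58 to 9.71 in the 3 females and 2.49 to 3.14 in the 5 males (6.99 higher in females, SE 0.16, adjusted p = 1.2e-08). The Y-linked genes Eif2s3y (-5.12, SE 0.18), Kdm5d (-3.10, SE 0.17) and Uty (-2.72, SE 0.27) fell in females, all adjusted for genotype. These levels matched the labelled sex in all 8 samples. Gpx3, a secreted glutathione peroxidase encoded on chromosome 11, was lower by 1.45 in females (SE 0.17, adjusted p = 0.0172), but the call was lost in 9 alternatives, among them those without any 1 of homozygote replicates 1, 2, 3 and 4 (adjusted p = 0.242, 0.132, 0.141 and 0.117) and with genotype out of the model (-1.29). Uty lost it without homozygote replicate 1 or 2 (adjusted p = 0.0681 and 0.0553). These 5 genes (1 higher and 4 lower) were all that passed in limma. The X-linked genes Kdm6a (0.98, SE 0.15) and Eif2s3x (0.56, SE 0.08) had adjusted p = 0.107, Dio2, which activates thyroid hormone, measured 1.01 (0.67 without heterozygote replicate 4) and Plpp3, a lipid phosphatase, -0.79 (both adjusted p = 0.445). Without heterozygote replicate 4, the only heterozygous female, 75 genes passed, and without homozygote replicate 1 or homozygote replicate 2 only 3.

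The test of a genotype difference that depends on sex passed for 18 genes. Each sex had 2 homozygotes, and the females 1 heterozygote. Sex therefore cannot be told apart from differences between individual animals or dissections. The count of 18 was not set against other splits of the arrays. In the 2 homozygous males Lcn2, the acute-phase protein lipocalin 2, reached 11.29 and 11.44 against 3.09 to 3.34 in heterozygous males, a difference of 8.11 (SE 0.19). In females it differed by 1.22 (SE 0.25), so that the female minus male term was -6.89 (SE 0.32, adjusted p = 4.14e-05). Timp1, an inhibitor of metalloproteinases, had a term of -6.12 (SE 0.49, adjusted p = 0.00122) and Steap4, a metalloreductase encoded near Pex1 and induced by inflammation, one of -5.72 (SE 0.35, adjusted p = 0.000134). In the 2 homozygous females the crystallin Crygd reached 11.75 and 11.56 against 4.27 in the heterozygous female (term 6.77, SE 0.56, adjusted p = 0.0013), and the small heat shock protein Hspb1 reached 9.86 and 9.71 against 5.58 (term 4.03, SE 0.24, adjusted p = 0.000134). The term of Cryga was 4.76 (SE 0.29, adjusted p = 0.000134).

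Of the 18 genes, 12 had a term below 0. They also included Saa3, Chil1, Cp and Serpina3n, which encode secreted proteins of inflammation or the acute phase, the MHC class II genes H2-Ab1, H2-Eb1 and H2-Aa, and 2610528A11Rik. For Sult3a1 the term of -1.90 rested on heterozygote replicate 4 alone (2.99, against 1.00 to 1.14 elsewhere). The 6 with a term above 0 were Cryga, Crygb, Crygd, Crygf, Hspb1 and Dnase2b, the nuclease that degrades DNA in lens fibres. In camera 9 lists passed for the interaction of genotype and sex with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.227). They included gliosis (adjusted p = 1.44e-20, and 0.244 as the adjusted p with an estimated correlation), with medians of 2.26 in males and 0.31 in females, and lens (3.05e-16, and 0.290), with -0.35 and 1.73. The other 7 were microglia (1.23e-15), interferon (6.28e-06), immediate early genes (0.000218), the unfolded protein response (0.000794), bipolar cells (0.0446), pigment epithelium (0.0463) and the clock (0.0463), with adjusted p from 0.227 to 0.645 with an estimated correlation. Only 1 heterozygous female was measured, so the test assumes that its group varies like the others. Without heterozygote replicate 3 the count of genes was 53 and without homozygote replicate 3 it was 11, and without heterozygote replicate 4 the term cannot be estimated.

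**Figure D3:**
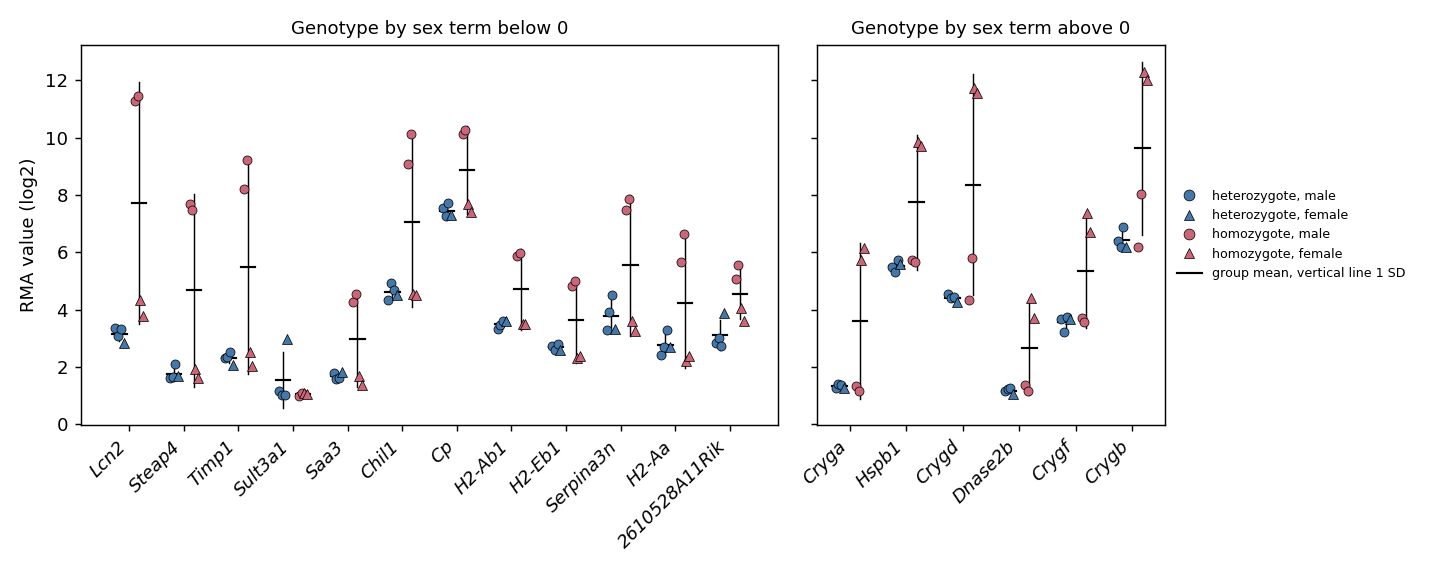
Expression of the 18 genes past the threshold for the interaction of genotype and sex, in each retina (vertical axis, RMA value on the log2 scale). Colours and symbols are those used for the cone genes, with means as bars and 1 SD as vertical lines (n = 4 each). Lcn2 lies at 11.29 and 11.44 in the male homozygotes, and Crygd at 11.75 and 11.56 in the female homozygotes. Sult3a1 is set apart by the single heterozygous female.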

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

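The tests of photoreceptor loss, RNA degradation, unequal sexes, blood, surrounding tissue, individual animals and a single source of crystallin signal were chosen only after the results were seen. The counts over other splits of the arrays and the bound for further lens genes were fixed beforehand, but the signal limits applied to those lens genes were added after their values were seen.

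Among the 35 splits of the 8 arrays into 4 and 4, only the real one (1 of 35) gave as many as 3 genes past the threshold, and the highest other count was 1. This argues against chance for the genotype count but does not exclude it, since 1 of 35 is the smallest share that the design allows. For the gene lists 5 of 35 splits gave at least the real 11, and the highest other, 17, set heterozygote replicates 1 and 2 with homozygote replicates 3 and 4. Chance cannot be excluded for the number of lists. For sex, 4 of 56 splits gave at least the real 5 genes, and the highest other, 29, set heterozygote replicates 1, 2 and 4 apart, so this share alone cannot exclude chance for the count of 5. It does not put the sex-linked genes in doubt, since Xist, Eif2s3y, Kdm5d and Uty, 4 of the 5, parted the sexes without overlap in all 8 animals. With genotype in the model the split of 29 sets heterozygote replicate 3 alone against the other heterozygotes, so the structure of the samples it points to rests on 1 array.

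Cone genes were lower in all 4 homozygotes. Loss of photoreceptors of every type would not give this pattern alone: the cone-list median minus that of 13 rod and shared photoreceptor genes of middle signal was 0.02 ± 0.06 in heterozygotes and -0.47 ± 0.11 in homozygotes (SD, n = 4 each), a difference of -0.484 (exact permutation p = 0.0286). RNA degradation in homozygotes would have raised their actin 3′ minus 5′ value, which was lower by -0.379. That argues only against more degraded RNA in homozygotes. The value was higher in every heterozygote (2.63 to 3.04) than in any homozygote (2.11 to 2.55). An effect of RNA quality in that direction cannot be told apart from genotype. With sex in the model 5 cone genes passed, all lower, so unequal sexes are not the whole cause. A lower share of cones or lower transcription in cones, both differences that the genotype could bring, remain open and were not told apart by a test.

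Acute-phase and immune genes were high in the 2 male homozygotes, as in Lcn2 (term -6.889), Steap4 (-5.723) and Timp1 (-6.116), where the test of the genotype difference by sex passed. Carry-over of sclera, choroid or pigment epithelium is argued against by the median of 26 of their genes, -0.0491 between the male homozygotes and the 6 other animals. Of the 11 pigment genes among them, 4 were lower in every homozygote than in any heterozygote, which weakens this comparison. Dct, 1 of these, measured 3.27 and 5.02 in the males and 4.59 and 4.27 in the female homozygotes, so it does not set the males apart. Some of the 26, such as Ckm and Lum (means of 2.57 and 1.58), are near background, so a small carry-over of muscle or sclera could be missed. The blood list's median was 0.0914, with S100a8 and S100a9 above all 6 others, but 6 of its 7 genes averaged below 3, near background, so blood cannot be told apart from a response of the tissue. Whether the 2 animals differ because of sex or as individuals also stays open: the 4 homozygotes can be parted into pairs in only 3 ways, and 1 of them is by sex. Sex, a biological difference that the design names, may account for the pattern but was not tested apart from the individuals.

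Gamma-crystallin genes and Hspb1 were high in the 2 female homozygotes, with terms of 6.773 for Crygd, 4.762 for Cryga and 4.03 for Hspb1. If lens tissue were the one source of all crystallin signal, Crygd minus Mip would keep 1 value, but the highest value of the 6 other animals lay 4.24 below the lower of the 2 females (a difference of -4.24). Lens tissue carried over in those dissections, on top of a retinal signal, remains a candidate explanation: of the 13 measured lens-list genes 10 were highest in those 2 animals. Against it, 8 further lens genes had a median of 0.0511, under the bound of 0.2 set beforehand, 0 of them were above all 6 other animals, and dim genes can rise, as Cryga did (1.15 to 1.39 elsewhere, 5.73 and 6.15 in the females). The bound was not taken to settle it, since 4 of the 8 averaged below 3, near background, and 2 above 7 in these retinas (Tdrd7 and Fyco1), where a small share of lens would hardly show. Bfsp1, a lens filament gene, stood at 8.55 and 8.45 against 3.87 to 5.46. Dnase2b, the lens fibre nuclease, stood at 4.39 and 3.70 against 1.05 to 1.37. Both genes were picked after their values were seen. Lens tissue, a response of the female retina and differences between individual animals or dissections all stay open.

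Single animals stood apart from the other 3 of their group in 15 of 238 tests, with 11.9 expected by chance, since about 1 in 20 groups does. Pde6h measured 10.19 in heterozygote replicate 4 (others 9.75 on average) and Dio2 6.154 in the same animal (others 4.69). In homozygote replicate 1, Cyp4a14 measured 2.888 (others 4.01), Alas2 2.095 (others 1.71), Fabp7 1.978 (others 2.65), Kdr 7.29 (others 6.85) and Npas2 1.795 (others 1.45). In homozygote replicate 2, Nefm measured 7.733 (others 8.09) and Tmem243 7.086 (others 6.56). Vwf measured 1.38 in heterozygote replicate 1 (others 1.79), Cyc1 8.019 in heterozygote replicate 3 (others 8.12) and Tmem243 6.605 in heterozygote replicate 2 (others 6.41). Among list medians, the microglia list stood at 0.2526 in heterozygote replicate 3 (others -0.13), the blood list at -0.3189 in homozygote replicate 3 (others 0.08) and the PPAR alpha list at -0.08812 in heterozygote replicate 2 (others 0.01).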

How the results depend on the processing

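The comparisons with the male or the female homozygotes left out, the permutation of list medians and the list test of the interaction were chosen only after the results were seen. The genotype count of 3 became 10 with sex in the model (4 higher and 6 lower, the 3 cone genes among them), 5 with robust variances, 5 at an adjusted threshold of 0.10, 716 at an unadjusted p under 0.05 and 0 without moderation of the variances. It was 69 in males only (65 higher and 4 lower), 15 with the male and 101 with the female homozygotes left out (95 higher), and 0 to 3 without 1 array. As a replicate block, the replicate number left 0 genes. The values showed no clear pairing by number: deviations of same-numbered animals correlated at 0.341, -0.0503, -0.0770 and 0.0863, and only number 1 found its best match in its own number. With 4 pairs this cannot exclude a litter or day shared by number. The sex count of 5 became 12 over single probe sets, 2 with genes of mean under 5 left out, 2 with genes below the median signal left out, 3 without moderation, 635 unadjusted and 3 to 75 without 1 array. The interaction count of 18 became 6 and 7 under the same filters, 1 without moderation (Dmkn), 448 unadjusted and 11 to 53 without 1 array. The 11 lists became 5 and 5 under the filters, 7 with array weights, 7 with the male homozygotes left out, 0 with an estimated correlation, 1 with fry, 0 by exact permutation of medians and 6 to 13 without 1 array. Under the filters fewer genes are tested, and without an array fewer samples. For the other changes the cause was not tested. The sign of the list call turned for pigment epithelium with genes of mean under 5 left out (mean difference -0.458, adjusted p = 0.520), and for lens in males only (-0.314) and with the female homozygotes left out (-0.2544). Of 3039 values of single genes and lists under the alternatives, 2833 kept their side of the threshold, 142 lost the call with the same direction, 61 gained one and 3 are the list calls just named. The sign of the value itself differed from the reported one in 82 values of 22 genes or lists, 79 of which kept their side of the threshold. Besides lens these were results that had not passed, and 1 passed with the other sign (the clock list with the male homozygotes left out, 0.1256, adjusted p = 0.0475). The list tests were not run without moderation, without trend, with robust variances or unadjusted, and the interaction could not be fitted without its only heterozygous female, in males only or with a sex's homozygotes left out. Signal near background limits dim genes, among them Cyp4a14, Alas2, P2ry12, Gfap, Ehhadh, Acaa1b, Fas, Casp8, Igfbp1, Ly75, Pcdhb19, Ect2 and Vwf.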

Other observations

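All values in this part were chosen only after the results were seen, and none was tested further.

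Melanin pathway genes varied widely within the heterozygotes, and several pigment genes also parted the genotypes. In heterozygote replicate 3, Dct measured 9.71, Tyrp1 8.68, Pmel 8.44 and Tyr 6.33, while the 4 homozygotes lay between 3.27 and 5.02, 2.94 and 4.00, 3.30 and 3.68, and 1.67 and 2.44. Dct was lower in every homozygote than in any heterozygote, whose lowest value was 5.87. Counting Dct, 4 of the 11 measured genes of the pigment epithelium and melanocyte list parted the genotypes in this way. Rpe65, partly near background, and Ttr were picked from the pigment epithelium genes and did not follow, which does not cover that tissue's other genes. Rpe65, the retinoid isomerase, measured 2.57 to 3.97 in homozygotes and 2.45 to 3.82 in heterozygotes, and Ttr, the transthyretin gene, 9.29 to 10.19 and 7.84 to 9.79. Gpnmb, a glycoprotein of melanosomes and phagocytes, measured 7.73 in heterozygote replicate 3 and 3.47 to 5.14 elsewhere.

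The beta-crystallin and lens membrane genes varied across animals of both genotypes. Mip, the lens aquaporin, measured 6.32 to 8.56 in heterozygotes, 6.05 and 7.54 in male homozygotes and 8.83 and 9.03 in female homozygotes, and Crybb3 measured 7.80 to 10.02, 8.19 and 9.19, and 10.93 and 10.66. Cryab, which the retina also expresses, measured 11.57 to 12.24 in all 8 animals. Among metallothioneins, Mt2 measured 9.9996 and 10.59 in the male homozygotes and 6.85 to 8.29 in the 6 other animals, and Mt1 measured 9.91 and 10.44 against 7.70 to 8.86. Stat3, a transcription factor of cytokine signalling, was above all heterozygotes in all 4 homozygotes (7.16, 7.32, 6.33 and 6.14, against 5.54 to 6.07).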
